A study of Homo sapiens with 6 samples.

How the data were processed

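Poly(A)-selected RNA from 6 samples of human iPSC-derived microglia was sequenced, 3 libraries with a SORL1 knockout and 3 wild type, each after IFN-γ at 10 ng/ml for 48 h, per the labels' protocols. The authors deposited gene-level estimated counts and a table of TPM (transcript abundance corrected for length and scaled to a fixed total) for the same libraries. Quantification was done with kallisto 0.44.0 on GRCh38.p12, per the submitters' processing notes; the annotation release is not given in the sources used here. The deposited estimated counts were already whole numbers for all 36459 genes, so rounding changed no value, and the deposited TPM values sum to 1000000 in every library. Estimated counts from kallisto share reads between near-identical transcripts by a model, so values of gene copies and pseudogenes are less certain than those of unique genes. In the TPM values 27 gene names had turned into dates, and these were left out of TPM-based values. Gene positions came from GENCODE 29 (GRCh38), in which 35346 of the gene names (96.9%) matched once.

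Samples were grouped by the genotype in their labels. A batch label differs in every sample, so batch cannot be a covariate and cannot be told apart from the libraries themselves. The main test was edgeR 4.0.16 (quasi-likelihood F test, two-sided) in R 4.3.3, with TMM scaling, filterByExpr, genotype as the single term and a Benjamini-Hochberg adjusted p threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes unless said otherwise, and log2 CPM adds a prior count of 2. Gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, over 27 of the 29 lists, those with at least 5 tested genes. In these lists 8 symbols were matched through older names and 2 were not found.

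Before the data were examined, the groups, the main design, the gene lists, the alternatives and the rule for naming genes were fixed. The rule names SORL1; the 10 largest rises and 10 largest falls among genes with adjusted p below 0.05, a mean TPM of at least 1 in the higher group, no overlap between the groups' 3 values and a gene symbol; and up to 4 genes per list with the smallest adjusted p. The values of 1 gene that the rule names are not reported here. SQLE, C3, ENO2, APOC1, APOC2, PNPLA2, CPA3, CLC, PDCD1LG2, P2RY14, UBASH3B, SIAE and ADAMTS15 fall outside it and were named after their values were seen, as were genes named only for a change without the library labelled wild-type replicate 3, for their level in single libraries or as examples of markers below the test's filter.

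Depth ran from 16101884 to 20858610 estimated counts per library, with 11.3 to 12.7% in the 10 most abundant genes. A count of 0 allows a level of up to 0.144 to 0.186 CPM (3 counts), which limits genes near the floor. No pair of libraries within a group differed by less than sampling noise: chi-square per degree of freedom was 6.07 to 12.4 between knockout libraries, 8.03 between wild-type replicates 1 and 2, and 68.2 to 69.2 for pairs with the library labelled wild-type replicate 3.

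The tests were tested on simulated data with the real libraries' means and sizes, in 5 runs over 12858 genes with 100 genes changed 2-fold and 100 changed 4-fold per run. For this comparison edgeR recovered 70.6% of the 2-fold and 97% of the 4-fold changes with 6.47% of calls false, limma-voom 69.2% and 96.6% with 6.01% false, and DESeq2 1.42.0 78.6% and 97.2% with 19.4% false. The list test called a list of 30 genes raised 1.5-fold in 5 of 5 runs and 0 of 100 unchanged lists. Simulated genes vary independently, so the list test was not tried there on correlated genes. Each simulated gene had the same dispersion in every library, so no simulated library stood apart as the library labelled wild-type replicate 3 does. These rates may therefore not hold for the real libraries.

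The alternatives were other scalings (DESeq2 size factors, upper quartile, total count), no filter or a filter of 1 CPM in 3 libraries, the replicate number as a block, DESeq2, limma-voom, edgeR with robust fitting, limma on log2(TPM + 1) and log2(TPM + 0.1), length offsets from the ratio of estimated counts to TPM, a fold limit of 1.5, and each library left out; for lists, an estimated correlation and fry. Figures were drawn with matplotlib.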

Results

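Bulk messenger RNA was profiled in microglia differentiated from a human induced pluripotent stem cell line that had been reprogrammed with episomal vectors. Microglia are the resident macrophages of the brain. Of the 6 libraries, 3 came from cells with a knockout of SORL1, which encodes a sorting receptor that carries cargo between endosomes, the Golgi and the cell surface and is a risk gene for Alzheimer disease, and 3 came from wild-type cells. Every library was made after 48 h with interferon gamma (IFN-γ) at 10 ng/ml, so the comparison is between genotypes within the cytokine-treated state; untreated cells were not analysed here. Library totals were 19872032, 18689969 and 16101884 estimated counts in knockout replicates 1, 2 and 3, and 17433916, 20858610 and 17274634 in wild-type replicates 1, 2 and 3. The labels do not say whether the replicates were separate cultures or whether more than 1 knockout clone was used. The p-values therefore measure only the spread between these samples, which may be technical, and genotype cannot be separated from clone or culture.

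SORL1 lies on chromosome 11 of GRCh38, from position 121452203 to 121633693 on the plus strand. Its transcript stood at 0.865, 0.663 and 1.02 CPM (counts scaled to a library total of 1000000) in the knockout libraries, from 17, 12 and 16 counts. In the wild-type libraries it stood at 6.77 CPM in replicate 1 and 12.8 CPM in replicate 2, but at 1.60 CPM, from 28 counts, in the library labelled wild-type replicate 3. That library held 1.90 times the SORL1 level of the pooled knockout libraries (95% Poisson interval 1.14 to 3.12), and replicates 1 and 2 pooled held 6.27 times its level (4.27 to 9.56); both intervals cover counting error only. Over all 6 libraries SORL1 had a log2 fold change of -3.06 (SE 0.72, n = 3 per group) and did not pass the threshold of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0611). Without the library labelled wild-type replicate 3 the value was -3.53 (adjusted p = 0.000235). The low SORL1 level of that library goes against its label in part, and every value over all 6 libraries draws on it.

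**Figure D1:**
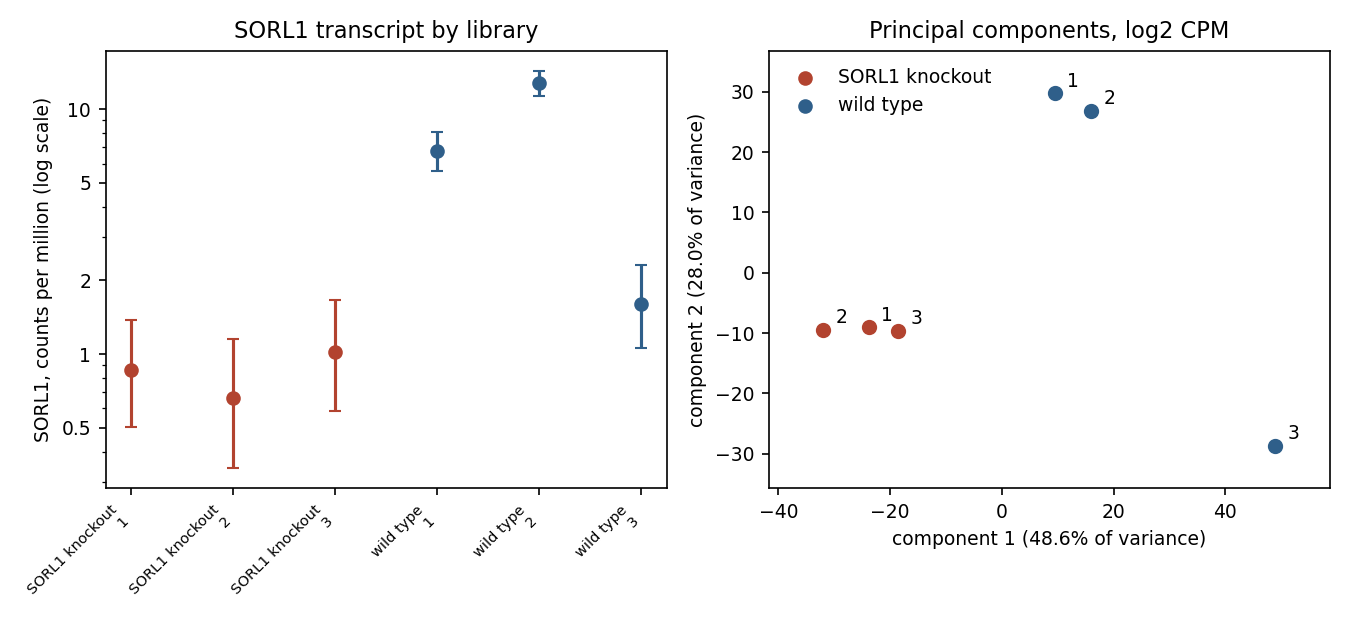
Left, SORL1 in each library in CPM on a log axis, with 95% Poisson intervals as bars; the library labelled wild-type replicate 3 sits at 1.60 CPM, next to the knockout libraries at 0.663 to 1.02 CPM. Right, each library on the first and second principal components of log2 CPM, the first holding 48.6% of the variance, with replicate numbers beside the points; the library labelled wild-type replicate 3 lies apart from every other library.

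The comparison of genotypes asks how loss of SORL1 alters the transcriptome of microglia under IFN-γ. Knockout libraries held more transcript of the chemokine gene CXCL9 and the scavenger receptor gene MARCO, and less of the microglial lipid receptor gene TREM2 and the lysosomal lipase gene LIPA. CXCL9, a T-cell chemokine induced by IFN-γ, stood at 10034 ± 775 CPM in the knockout and 1898 ± 732 CPM in the wild type (SD, n = 3 each). MARCO stood at 514 ± 180 against 46.2 ± 14.3 CPM, an 11.1-fold difference. TREM2 stood at 82.2 ± 10.0 against 237 ± 37.6 CPM, and LIPA at 3539 ± 489 against 6234 ± 327 CPM. Of 12858 genes tested, 672 passed the threshold, 379 higher and 293 lower in the knockout, of which 163 and 95 differed at least 2-fold. With scaling by total count alone the split was 286 higher and 451 lower.

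The largest rises under the naming rule were in TTC4P1 (log2 fold change 3.78), MFAP5 (3.76), MARCO (3.47), SAA2 (3.01), RANBP3L (2.88), BCL2L14 (2.81), TNFAIP8L3 (2.79), SPC25 (2.76), RGMA (2.76) and ACOD1 (2.76). Without the library labelled wild-type replicate 3, RANBP3L stood at 4.02, MFAP5 at 4.54 and RGMA at 3.57, each over 1.5 times further in fold. ACOD1 makes the antimicrobial metabolite itaconate in activated macrophages, SAA2 is an acute-phase protein, and SPC25 is a kinetochore component. TTC4P1 is a processed pseudogene and SAA2 a near copy of SAA1, so both values are uncertain where reads were shared between copies. Some of these rises rest on wild-type means at or near the floor of 3 counts. TTC4P1 stood at 3.25 CPM in the knockout against 0.235 in the wild type, SAA2 at 1.03 against 0.125 and SPC25 at 0.998 against 0.142. The size of these folds is therefore uncertain. The largest falls under that rule were in SPON2 (-3.38), DPP4 (-3.11), GALNT14 (-2.99), HTRA1 (-2.83), VWF (-2.70), PLD4 (-2.57), PNMA8B (-2.48), CCDC8 (-2.37), SULF2 (-2.34) and CAMK2B (-2.33). With length offsets SAA2 (2.50), SPC25 (3.08) and CAMK2B (-1.33) did not pass. SAA2 stood at 3.65 without wild-type replicate 1, and CCDC8 at -2.97, not past the threshold, without knockout replicate 1. Without the library labelled wild-type replicate 3 SPON2 stood at -2.21, DPP4 at -2.40 and HTRA1 at -2.20, so the order of these genes depends on it, and SPON2 itself was at 444 CPM there against 89.1 and 97.0 CPM in wild-type replicates 1 and 2. DPP4 is a cell-surface peptidase that trims chemokines, HTRA1 a secreted serine protease, and SULF2 an enzyme that removes sulfate from heparan chains. Among these 20 genes the adjusted p ran from 0.00912 for SULF2 to 0.0408 for RANBP3L.

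**Figure D2:**
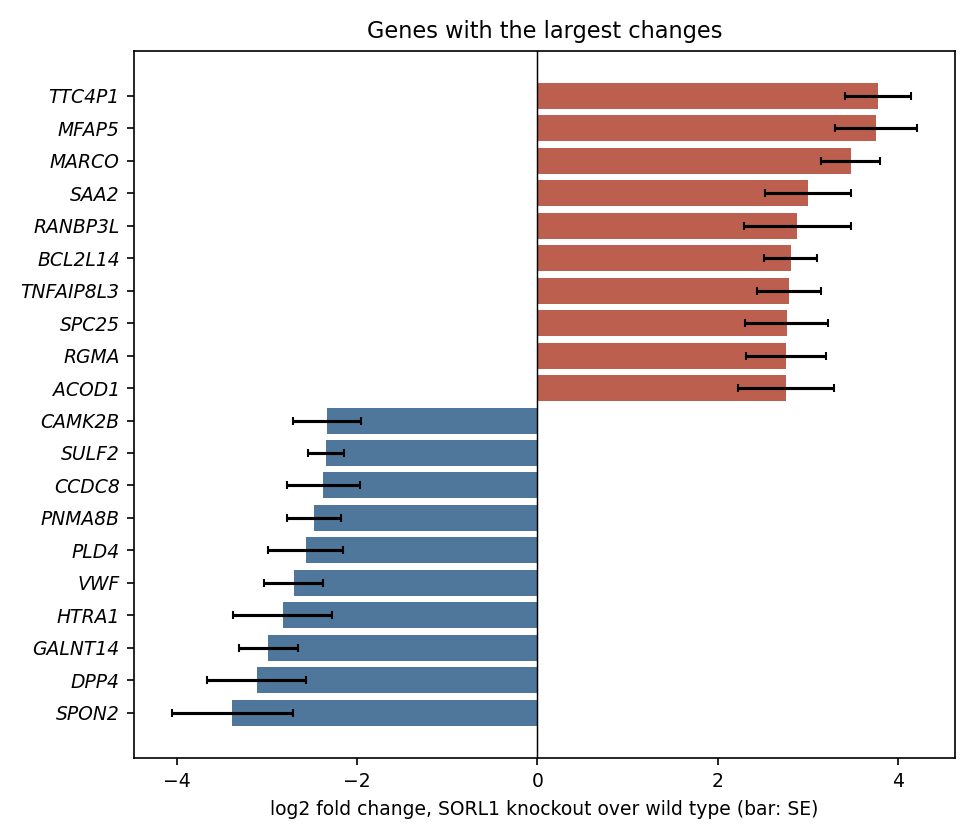
Log2 fold change, knockout over wild type, of the 10 genes with the largest rise and the 10 with the largest fall by the naming rule; thin bars are standard errors, red marks higher and blue lower in the knockout. Values run from 3.78 for TTC4P1 to -3.38 for SPON2.

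Of 51 measured genes of the type II interferon response, 10 rose, 0 fell and 41 did not pass, with 31 higher when adjusted over the list alone. UBD, a ubiquitin-like modifier, stood at 264 ± 12.6 CPM in the knockout and 65.9 ± 12.5 in the wild type. On the log2 scale CXCL9 rose by 2.40 (SE 0.29), the guanylate-binding protein gene GBP2 by 0.98 (SE 0.10) and the transcription factor gene BATF2 by 0.77 (SE 0.07). The list's camera test gave adjusted p = 4.0e-22 with the preset correlation and adjusted p = 0.506 with an estimated correlation. The library labelled wild-type replicate 3 lay 0.77 log2 units below the other wild-type libraries on this list, and without it 31 genes rose and 2 fell, PDCD1LG2 (-0.54) and P2RY14 (-0.59). Type I interferon-stimulated genes, largely antiviral effectors, moved the same way: 15 of 40 rose and 0 fell, with 30 higher when adjusted over the list alone. Examples were IFI44L (1.48), CMPK2 (0.87), OAS2 (0.61) and DDX58, the RNA sensor RIG-I (0.43). Here the library labelled wild-type replicate 3 lay 0.06 above the other wild-type libraries and 31 genes rose without it. The camera adjusted p was 5.1e-20, and adjusted p = 0.349 with an estimated correlation of 0.148.

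Inflammatory cytokines and NF-κB targets rose in 12 of 42 genes and fell in 0, with 21 higher when adjusted over the list alone. CCL5 rose by 1.46 (SE 0.14), TNFAIP6 by 1.37 (SE 0.13), BIRC3 by 0.99 (SE 0.13) and CCL20 by 2.04 (SE 0.27). The list gave adjusted p = 3.7e-21 by camera at the preset correlation and adjusted p = 0.506 with an estimated correlation of 0.344. The library labelled wild-type replicate 3 lay -0.95 from the other wild-type libraries on this list, and 27 genes rose without it. Immediate early and heat shock genes included 4 of 32 that rose, EGR1 (2.04), EGR3 (2.02), DUSP1 (1.11) and HSPA1B (0.65), and 4 when adjusted over the list alone (camera adjusted p = 0.00253; adjusted p = 0.517 with an estimated correlation). Leaving out the library labelled wild-type replicate 3 added ATF3, IER3, NR4A3 and HSPA1A to those that rose, 8 in all, and HSPD1 (-0.28) fell.

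**Figure D3:**
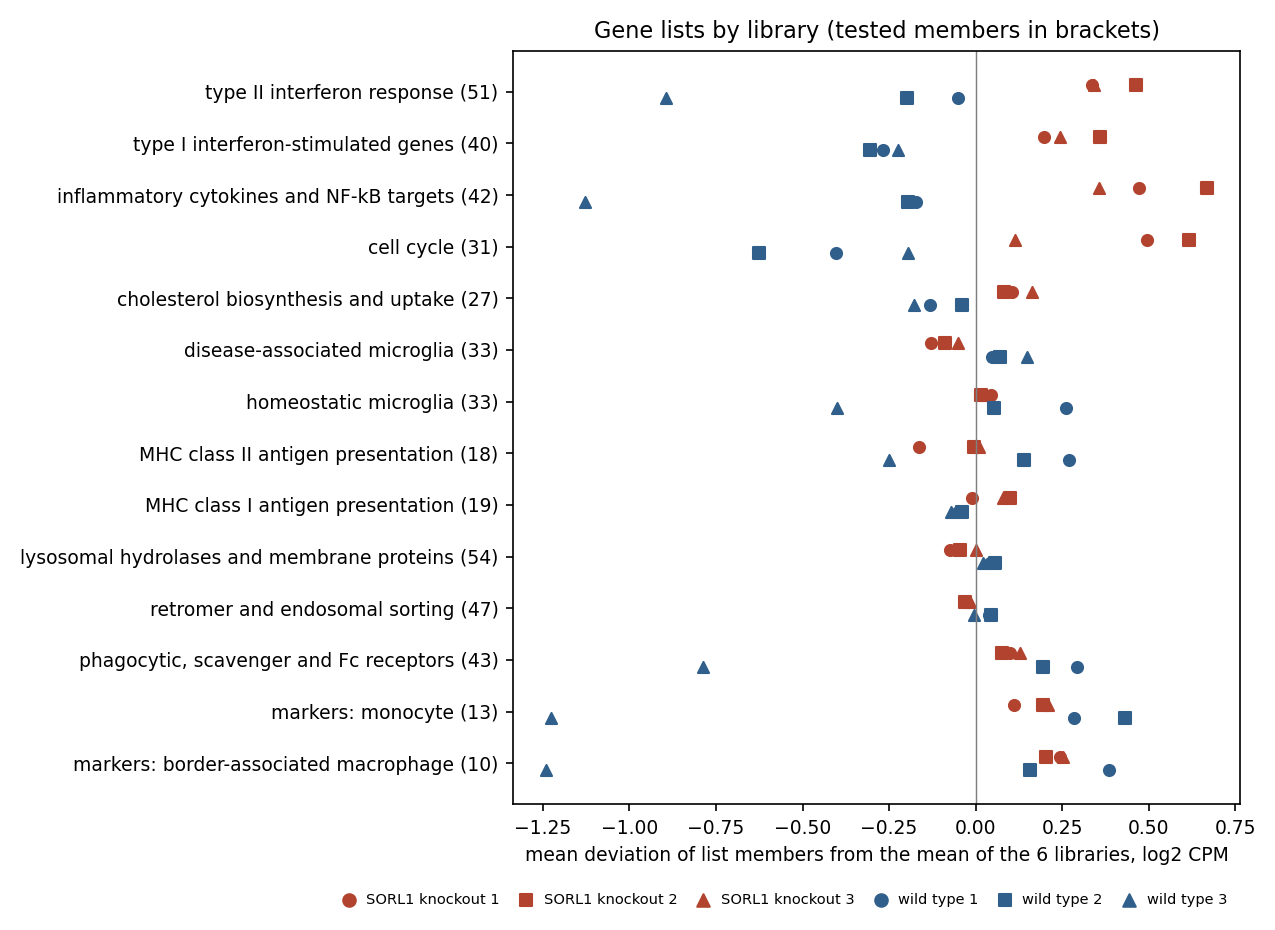
Mean deviation of each list's tested genes from the mean of the 6 libraries, in log2 CPM, with 1 point per library (red knockout, blue wild type; circle, square and triangle for replicates 1, 2 and 3). Knockout libraries lie above every wild-type library on the interferon, inflammatory, cell cycle and cholesterol lists, and the library labelled wild-type replicate 3 lies between -0.79 and -1.24 on the type II interferon, inflammatory, phagocytic receptor, monocyte and border-associated macrophage lists.

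Genes of the disease-associated microglial state, the lipid-handling programme seen around amyloid plaques, included 6 of 33 that fell and 0 that rose, with 4 higher and 10 lower when adjusted over the list alone. TREM2 fell by 1.53 (SE 0.14), CD9 by 1.46 (SE 0.26), LIPA by 0.82 (SE 0.12) and the lipoprotein lipase gene LPL by 0.81 (SE 0.12). Camera gave adjusted p = 0.00343, and adjusted p = 0.506 with an estimated correlation; without the library labelled wild-type replicate 3, 8 genes rose and 10 fell. In the list of homeostatic microglial genes 7 of 33 fell and 1, the complement gene C3 (1.15), rose, with 9 and 3 when adjusted over the list alone. MERTK, a receptor for apoptotic cells, fell by 1.07 (SE 0.08), GPR34 by 1.04 and MEF2A by 0.54. That list's median was 0.04 while its mean and its test were below 0 (adjusted p = 0.104). The library labelled wild-type replicate 3 lay -0.56 from the other wild-type libraries on it, and without that library C3, TMEM119, SELPLG and CD33 rose and 10 genes fell (camera adjusted p = 0.0330; adjusted p = 0.429 with an estimated correlation). Of 38 genes at Alzheimer disease risk loci 3 fell, TREM2, ACE (-1.53) and ABI3 (-0.55), and 0 rose; CTSH had a log2 fold change of 0.99 and did not pass. Adjusted over the list alone, 2 were higher and 4 lower (camera adjusted p = 0.191). With the library labelled wild-type replicate 3 left out, CTSH (0.77), CD33 (0.71), MS4A7 (0.66) and CLU (0.98) rose and 9 genes fell. The gene lists overlap: 17 of the 33 disease-associated, 7 of the 33 homeostatic and 13 of the 38 risk-locus genes were also in another list. TREM2 counts as a fall in each of these 3 lists, so their counts are not separate findings.

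Of 54 lysosomal hydrolase and membrane protein genes 4 fell and 0 rose, with 2 higher and 5 lower when adjusted over the list alone. Among them were LIPA, the glucuronidase gene GUSB (-0.77) and the sphingomyelinase gene SMPD1 (-0.41), and the list did not pass (camera adjusted p = 0.102). With the library labelled wild-type replicate 3 left out, CTSC (0.31), CTSH (0.77), NPC1 (0.29) and CD63 (0.24) rose and 7 genes fell. In the list of retromer and endosomal sorting genes, the machinery SORL1 works with, SNX5 fell by 0.53 (SE 0.07) and the other 46 did not pass, with 1 lower when adjusted over the list alone (camera adjusted p = 0.195). In cholesterol biosynthesis and uptake 5 of 27 genes rose and 0 fell, with 10 higher when adjusted over the list alone: INSIG1 (0.53), LSS (0.42), MVD (0.41), SQLE (0.39) and HMGCS1 (0.33), of which INSIG1 alone passed with length offsets. Camera gave adjusted p = 4.7e-05, and adjusted p = 0.506 with an estimated correlation. Lipid efflux, storage and liver X receptor targets went both ways, with CH25H (2.31), PLTP (1.21) and PNPLA2 (0.60) higher and FABP3 (-1.21), APOC1 (-0.94), APOC2 (-0.82) and LPL lower of 34, and 7 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.389).

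Few antigen presentation genes passed. In the class I list TAP1, the peptide transporter, rose by 0.37 (SE 0.08), and the other 18 genes did not pass, with 3 higher when adjusted over the list alone (camera adjusted p = 0.104). In the class II list the protease gene LGMN fell by 0.59 (SE 0.13) and 17 did not pass, HLA-DMB (-0.60), HLA-DRB1 (-0.36) and HLA-DMA (-0.34) among them, with 4 lower when adjusted over the list alone (camera adjusted p = 0.0618). The library labelled wild-type replicate 3 lay -0.45 from the other wild-type libraries on the class II list, and without it 12 class II genes fell and CD80 (0.54) rose (camera adjusted p = 2.1e-05; adjusted p = 0.429 with an estimated correlation). Of 43 phagocytic, scavenger and Fc receptor genes, MARCO, TLR7 (1.52) and ITGAV (0.51) rose and MERTK fell, with 3 and 1 when adjusted over the list alone (camera adjusted p = 0.310). The library labelled wild-type replicate 3 lay -1.03 from the other wild-type libraries on that list, and without it 8 genes rose and 10 fell, with a mean of -0.15 against 0.06 (camera adjusted p = 0.119).

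Cell cycle genes were higher in the knockout, with 7 of 31 rising, 0 falling and 18 higher when adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, rose by 2.15 (SE 0.24), MKI67 by 1.84 (SE 0.27), STMN1 by 1.17 (SE 0.20) and TPX2 by 0.76 (SE 0.15); MKI67, STMN1 and TPX2 did not pass with length offsets. The list gave adjusted p = 3.5e-12 by camera at the preset correlation and adjusted p = 0.506 with an estimated correlation of 0.519. Of 32 genes 20 rose without the library labelled wild-type replicate 3. Of 7 tested pluripotent stem cell markers LIN28B rose by 0.85 and 6 did not pass, with 1 higher when adjusted over the list alone (camera adjusted p = 0.104). On that list the library labelled wild-type replicate 3 lay 0.76 above the other wild-type libraries, and without it LIN28B (0.75), SOX2 (2.39) and L1TD1 (1.02) rose (camera adjusted p = 0.00161; adjusted p = 0.294 with an estimated correlation). Among mitochondrially encoded transcripts MT-ND1 rose by 0.49 and 12 did not pass, with 1 higher when adjusted over the list alone (camera adjusted p = 0.0134; adjusted p = 0.572 with an estimated correlation). Mitochondrial transcripts took 2.96, 3.07 and 3.46% of counts in knockout replicates 1, 2 and 3, and 2.56, 2.59 and 3.15% in wild-type replicates 1, 2 and 3.

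Whether the 672 genes passed the threshold depended on single libraries. Each fit with 1 library left out had 3 residual degrees of freedom, and every main call still tested kept its sign. Without knockout replicate 1 this held for 669 of 669 such calls. By the edgeR test 0 genes passed without knockout replicate 1 (2114 at an unadjusted p under 0.05; DESeq2 743, limma-voom 0) or without knockout replicate 2 (2138; 742; 0). The count was 77 without knockout replicate 3, 380 without wild-type replicate 1, 114 without wild-type replicate 2, and 1972 (1116 higher, 856 lower, all 672 included) without the library labelled wild-type replicate 3. In the lists for which this is not given above, leaving that library out added HLA-F, TAPBP and NLRC5 in class I, FDFT1, FDPS, DHCR7, MSMO1 and EBP in cholesterol, FABP4, NR1H3, PLIN2 and ACSL1 in lipid efflux and MT-ND4, MT-CO1, MT-CO2 and MT-CO3 as higher, and APOE in lipid efflux and BIN1 and FURIN in retromer as lower. With length offsets 331 genes passed, and of other genes named above HSPA1B, LIN28B, MEF2A, SMPD1, SNX5, APOC1, TAP1, LGMN, TLR7 and ITGAV did not. Each of these kept its sign there: HSPA1B stood at 0.69, LIN28B at 0.79, MEF2A at -0.41, SMPD1 at -0.39 and SNX5 at -0.47. APOC1 stood at -0.93, TAP1 at 0.37, LGMN at -0.60, TLR7 at 1.47 and ITGAV at 0.53.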

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

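The quality-weighted fit and the joint list setting given here were chosen after seeing the data. The count of 672 changed genes stayed within 1.5 times under the other scalings, filters, limma-voom and robust fitting (655 to 795), which shared 579 to 672 of the main calls. It was 1336 with DESeq2, which made more false calls in simulation, 330 on log2(TPM + 1), 331 on log2(TPM + 0.1), 55 on log2(TPM + 1) over all genes, 331 with length offsets, 15 against a fold limit of 1.5, and 1911 with limma-voom library quality weights, which gave the library labelled wild-type replicate 3 a weight of 0.231; the cause was not tested, except that the fold limit asks for larger changes. With 1 library left out it ranged from 0 (without knockout replicate 1 or 2) to 1972 (without the library labelled wild-type replicate 3), and every main call still tested kept its sign. SORL1 ranged from -3.53 to -2.30 with 1 library left out and crossed the threshold without a filter (-3.07), with DESeq2 (-3.06), with length offsets (-2.93), with quality weights (-3.28) and without the library labelled wild-type replicate 3 (-3.53). It was -1.15 on log2(TPM + 1), a scale that understates low genes, and -2.38 on log2(TPM + 0.1); its adjusted p ran from 8.6e-05 to 0.232 over all settings, and the cause was not tested. Of 9 lists that passed, 0 passed with an estimated correlation, 2 by fry (type I interferon-stimulated genes and cholesterol), and 0 with an estimated correlation and the library labelled wild-type replicate 3 left out; leaving out 1 library gave 7 to 12. The estimated correlations of the 9 lists ran from 0.0707 (disease-associated microglia) to 0.706 (mitochondrially encoded transcripts). All lay above the preset 0.01, so the preset p-values overstate the evidence. Whether replicate numbers pair the samples stays open. Same-numbered libraries had correlations of deviations of 0.03, 0.04 and 0.12. Knockout replicates 1 and 3, wild-type replicate 2 and the library labelled wild-type replicate 3 correlated best with their own number in the other group. Knockout replicate 2 and wild-type replicate 1 did not. With the replicate block 498 genes passed, 408 of them among the 672, and 10 lists passed. TIE1, not called (-0.36), ranged from -0.71 without wild-type replicate 1 to 0.63 without the library labelled wild-type replicate 3, and was 0.52 with quality weights, and P2RY14, not called (-0.20), ranged from -0.59 without the library labelled wild-type replicate 3 to 0.16 without wild-type replicate 1. Of 88 named genes that passed, 0 changed sign; 88 fell short without knockout replicate 1 or 2, 67 without knockout replicate 3, 28 without wild-type replicate 1, 55 without wild-type replicate 2, 0 without the library labelled wild-type replicate 3, 32 on log2(TPM + 1), 33 on log2(TPM + 0.1), 70 on log2(TPM + 1) over all genes, 28 with length offsets, 14 with the block and at most 11 otherwise. With length offsets SAA2 stood at 2.50, CAMK2B at -1.33 and SYTL4 at 0.56 (adjusted p = 0.537). With 3 libraries per group the simulated test recovered 70.6% of 2-fold changes, so a gene that did not pass is not shown to be unchanged.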

Other observations

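Markers of other cell types and further pathways filled in the picture of these cultures. Among fibroblast and mesenchymal markers PDGFRA rose by 1.18 and PDGFRB by 1.10 on the log2 scale, and 9 of 11 did not pass (3 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.196). The oligodendrocyte-lineage transcription factor gene OLIG2 rose by 1.87 and the myelin gene MBP fell by 0.69 in a list of 11 neuron and macroglia markers (1 higher and 1 lower when adjusted over the list alone; adjusted p = 0.555). PDGFRB did not pass with length offsets. VWF fell among 7 endothelial markers (1 lower when adjusted over the list alone; adjusted p = 0.427), where the median was 0.11 and the mean (-0.31) and test were below 0. Without the library labelled wild-type replicate 3 the endothelial mean turned to 0.09 and the test to above 0 (camera adjusted p = 0.833). CSF3R (-0.98) fell among 13 monocyte markers (1 lower; adjusted p = 0.758). On the monocyte list the library labelled wild-type replicate 3 lay -1.58 from the other wild-type libraries, and without it S100A8, S100A9 and CD14 rose and FCN1, CSF3R, MNDA and CLEC12A fell, with a mean of -0.19 against 0.09 (camera adjusted p = 0.264). CCL13 rose by 2.21 among 13 dendritic cell markers (2 higher when adjusted over the list alone; adjusted p = 0.195) and did not pass with length offsets. PLTP rose among 10 border-associated macrophage markers, 9 of them shared with other lists (1 higher; camera adjusted p = 0.0273; adjusted p = 0.572 with an estimated correlation). On that list the library labelled wild-type replicate 3 lay -1.51 from the other wild-type libraries, and without it the call was lost (camera adjusted p = 0.833) and the mean turned to -0.15, with PLTP (1.13) and MS4A7 (0.66) higher and MRC1 (-1.49) lower. The tested mast cell and granulocyte markers were GATA2 (-0.13) and HPGDS (-1.20), and the tested erythroid and megakaryocyte markers KLF1 (-0.07) and GP1BA (-0.04), none past the threshold. Without the library labelled wild-type replicate 3, 5 mast cell and granulocyte markers were tested and CPA3 (-4.73), CLC (-3.81) and HPGDS (-0.75) fell, with a mean of -1.86 over the 5 (camera adjusted p = 0.000595; adjusted p = 0.294 with an estimated correlation). MPO, CPA3 and CLC passed the filter only there. With fewer wild-type libraries the filter can admit genes through wild-type replicates 1 and 2 alone, which can pull this mean and test below 0.

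In glycolysis and hypoxia NDRG1 (0.52), PFKFB3 (0.75), HK1 (0.41) and LDHA (0.30) rose and ENO2 (-0.77) fell of 32 genes, with 4 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.553); its median was -0.02 and its mean 0.02, and HK1, LDHA and ENO2 did not pass with length offsets. Lysosomal exocytosis genes SYTL4 (1.12) and SYT11 (0.34), both lost with length offsets, rose of 19 (3 higher when adjusted over the list alone; adjusted p = 0.297). MAP1LC3A rose by 1.27 among 28 autophagy genes (1 higher; adjusted p = 0.739). In the unfolded protein and integrated stress response 0 of 28 genes passed by edgeR, over all genes or adjusted over the list alone, and DNAJB9 stood at 0.28 and CHAC1 at 1.44 (camera adjusted p = 0.102). In the lists for which this is not given above, leaving out the library labelled wild-type replicate 3 added as higher CALD1 and TPM2 (fibroblast), SYP and SLC1A2 (neuron and macroglia), TIE1 and PLVAP (endothelial), CCR7, LAMP3 and FSCN1 (dendritic), PKM, ADM and HIF1A (glycolysis), SYT7 and STX11 (exocytosis), SQSTM1 and OPTN (autophagy) and ATF5 and DNAJB9 (unfolded protein). It added as lower COL1A2, S100B, CD1A, CLEC10A, SLC2A3, BNIP3, MXI1, LYST and TAX1BP1 in the same lists.

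All tests in the paragraphs below were set after the results they bear on, or values close to them, had been seen. The real grouping gave 672 genes and was the 1 split of 10 with as many, the highest other split giving 0 by edgeR (unadjusted 118 to 632; DESeq2 0 to 5; limma-voom 0). For lists, 6 of 10 splits gave as many as the 9 that passed, and the highest other gave 11. With 10 splits no share under 0.05 can be reached.

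The library labelled wild-type replicate 3 stood apart: its log2 CPM correlated across genes at 0.965 and 0.970 with the other wild-type libraries, which correlated at 0.990 with each other. It was at least 2-fold below them in 177 and above in 122 of 7529 genes, with CD163 at 46.5 CPM against 460 and 384, and CHIT1 at 6151 against 1326 and 1182. A knockout library under a wild-type label would sit near 1 on an axis from wild type (0) to knockout (1) over the genes called without it, and it sat at 0.246 (95% bootstrap interval 0.191 to 0.300). An admixture of knockout material would shift most of those genes toward the knockout, and 53.7% lay on that side. This share cannot exclude a partial admixture, because the library's other departures can hide a shared shift and its axis position lies above 0. Non-myeloid cells cannot be told apart from other sources: 36 of their markers averaged 0.188 above the other wild-type libraries (-0.22 to 0.62), and a second look, added when the first had not decided, found at most 2 markers of a list (COL5A2 and COL6A3) that reached 1 CPM (here on unscaled library totals) there alone among the wild-type libraries, with COL1A1 at 0.579 and COL3A1 at 0.0579 CPM on the same totals. The second look counted only markers below 1 CPM in wild-type replicates 1 and 2, so markers already above that were not covered. On TMM-scaled sizes the endothelial marker TIE1 stood at 495 CPM in this library against 112 and 137 in wild-type replicates 1 and 2. The endothelial marker ENG went the other way (425 against 548 and 522). DSP and COL6A2 were among this library's largest rises, by 3.56 and 2.92 log2 units. A difference in differentiation or in response to IFN-γ stays open and was not tested.

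The interferon and inflammatory lists were higher in the knockout libraries, though with an estimated correlation none passed (adjusted p = 0.506 for type II interferon, 0.506 for inflammatory and 0.349 for type I interferon genes). The low level of the library labelled wild-type replicate 3 does not account for the whole of it in these samples, since without that library the median over 132 genes was 0.490 (95% bootstrap interval 0.414 to 0.587, against 0.589 with it). That interval is for a median over genes and does not measure the spread between libraries. By list, leaving that library out lowered the median from 0.546 to 0.370 for type II interferon and from 0.910 to 0.629 for inflammatory genes. For type I interferon genes the median went from 0.478 to 0.507. Without that library each of the 3 lists gave a camera adjusted p = 0.294 with an estimated correlation. The choice among the scalings tried does not account for the higher level in the knockout either, as the lowest median over 3 other scalings was 0.522. Relative to TMM these scalings shifted all tested genes by -0.065 log2 at the furthest, so they could not have removed a difference of this size. A scaling error shared by all of them was not tested. Differences between clones or cultures stay open, because the design ties them to genotype, and a stronger response to IFN-γ in SORL1 knockout cells may be an explanation that untreated cells would be needed to test.

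On chromosome 11 beyond SORL1, 3 of 48 tested genes fell and 0 rose, UBASH3B (-1.30), SIAE (-0.72) and ADAMTS15 (-2.22), against 2.51 calls in either direction at the rate of all genes. Without the library labelled wild-type replicate 3, NRGN, SLC37A2, KCNJ1, C11orf45, ADAMTS8, FEZ1 and STT3A passed as well. Over all 6 libraries FEZ1 (1.25) and STT3A (0.29) stood above 0 and the other genes of that group below. UBASH3B, 1.02 Mb beyond SORL1, had the fifth smallest p of all genes. Loss of 1 of 2 copies of this arm end would put the median near -1. It was -0.0823 over all 6 libraries (95% bootstrap interval -0.16 to 0.00) and -0.128 without the library labelled wild-type replicate 3. Over all 6 libraries, 6.18% of 11254 autosomal windows of 48 genes had a median as low, so variation found along any chromosome can give such a value. That share is not given here without the library labelled wild-type replicate 3. A local effect on UBASH3B alone was not tested.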
